A study of Mus musculus with 76 samples.

How the data were processed

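Per the labels, RNA was extracted from liver, heart and SCN with TRIzol, 1.3 ug of total RNA per library was made into libraries with the NEBNext Ultra II kit, and reads were checked with FastQC 0.11.8 and aligned with STAR to mm10 (GRCm38). The STAR version, the counting program, its strand setting and its annotation release are not given. The authors deposited 1 table of raw read counts per gene, with a column for each of the 76 libraries; its values are whole numbers and its column totals differ between libraries. No normalised values were used. Each column was matched to its library by the title number and a tissue suffix. Of the 38129 entries in the table, 38038 (99.8%) matched GENCODE vM21 by Ensembl identifier, and gene coordinates were taken from it. Without a stated strand setting, reads of a gene and of an antisense neighbour cannot be told apart.

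Groups were defined by tissue, feeding, genotype and circadian time. In each tissue, genes were kept by edgeR's filterByExpr over the 8 groups, which left 14397 genes in liver, 16397 in heart and 18133 in SCN. Counts were scaled by TMM factors and fitted with a group-means model by edgeR 4.0.16 with robust quasi-likelihood dispersions. The contrasts were the time effect (CT12 minus CT0) in each feeding and genotype, the genotype effect (KO minus WT, averaged over times) and the genotype by time interaction in each feeding, the feeding by time interaction in each genotype, the feeding effect (TRF minus AL, averaged over genotype and time), and the interaction of all 3 factors. Time effects of heart and liver were compared in a joint model of both tissues (17656 genes). P values were adjusted by the method of Benjamini and Hochberg within a comparison, and a gene was called below 0.05. CPM values use the TMM factors, and shares of SCN or liver levels the library totals alone. Standard errors are the absolute log2 fold change over the square root of the F statistic. R 4.3.3 and Python 3.11.15 were used.

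Arntl and Vip were tested between genotypes on log2 of CPM plus 0.5. The 2-sided permutation test exchanged genotypes within each combination of feeding and time, over all 160000 divisions in SCN. Gene lists, 37 with 445 genes, were fixed before the data were examined; 2 genes had no entry (Hsd3b7 and Cyp3a41a), and the pancreas and adipose list of the liver had fewer than 2 tested members and was not tested. Lists were tested with fry from limma 3.58.1 for a shift in 1 direction, adjusted over the lists and comparisons of a tissue. Beside each count of called members stands the count adjusted over the list alone. The genes named were, by a rule fixed before the data were examined, core clock genes, Arntl and Vip, up to 4 members with the smallest adjusted p of each other list, and the 5 largest rises and falls among called genes with a mean of at least 5 CPM that separated all libraries of the compared groups. The last condition did not apply to interactions, and predicted genes, haemoglobins and immunoglobulin variable segments were left out of the largest changes. Results for 3 genes that met this rule or the rule for flagged values are not reported here.

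The methods were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 genes changed by known folds. Genes were drawn independently of each other, so variation shared across genes was not simulated. The changed genes were chosen at random among those above the lowest levels. Of genes changed 3-fold, 90% were recovered for the AL WT time effect in liver, 92% in heart and 98% in SCN. For the genotype by time interaction under AL, 66%, 84% and 80% were recovered.

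Alternatives planned before the data were examined were RLE factors in place of TMM, no filter beyond genes with 0 counts throughout, DESeq2 1.42.0, a fit of only the compared groups, leaving out each library in turn, leaving out TRF KO libraries 55 and 64, a term for the 4 AL libraries with 3-digit title numbers, and, between liver and heart, a block for the shared library number. After the data were seen, fits without these 4 libraries, without genes that brain RNA would raise in heart, without SCN libraries 1 and 10 of TRF WT, and with a term for the main axis between SCN libraries of a group were added, as were list tests without heart library 48 of AL WT CT12. Leaving out a library that reduces a group to 2 uses the spread pooled over the groups of the fit. Other splits of the libraries into groups of the same sizes were fitted in the same way, all of them up to 100 and otherwise 100 drawn at random, or 30 between liver and heart.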

Results

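RNA was sequenced from liver, heart and the suprachiasmatic nucleus (SCN, the hypothalamic seat of the central circadian clock) of mice sampled at circadian time (CT) 0 or 12. The mice were wild type (WT) or Bmal1-VIPKO (KO), in which the clock gene Bmal1 (symbol Arntl) is targeted in cells that make vasoactive intestinal peptide (Vip). They were fed ad libitum (AL) or by time-restricted feeding (TRF), with hours that the labels do not give. The 76 libraries fell into 24 groups of 3, except for 4 in each TRF KO group of liver and heart, and are named here by their title numbers. Each AL group held 1 library with a 3-digit title number (titles ending in AL_WT_CT0_401, AL_WT_CT12_404, AL_KO_CT0_407 and AL_KO_CT12_410), here called the 3-digit AL libraries. Total counts per library ran from 13502014 to 19018983. The comparisons ask how loss of Bmal1 in VIP cells and the timing of food alter the difference between CT12 and CT0 in peripheral clocks. Levels are given as CPM (counts scaled to the library total and its TMM factor), mean ± SD over the libraries of a group, and log2 fold changes with their standard errors.

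The targeted gene was read first. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 in GRCm38) averaged 23.3 ± 3.08 CPM in the 12 SCN libraries labelled KO and 22.4 ± 2.41 in the 12 labelled WT, with single libraries from 18.3 to 29.2 and from 18.2 to 27.5. That difference was not larger than its spread (two-sided permutation test within the 4 combinations of feeding and time, p 0.418). Bulk SCN tissue holds many cells that keep Arntl, so this level does not check the deletion. Vip (ENSMUSG00000019772, chromosome 10, 5639218 to 5647617 in GRCm38) averaged 0.494 ± 0.427 CPM in KO against 7.80 ± 5.68 in WT SCN (n = 12 each), a log2 difference of -2.70 (permutation p 3.75e-05, 1.50e-04 adjusted over 4 such tests). KO libraries held 0 to 1.28 CPM and WT libraries 0.504 to 17.7. A count of 0, found in 3 KO libraries, allows up to 0.163 to 0.178 CPM (3 counts, for counting error only). Across all genes, Vip did not pass in edgeR (adjusted p 0.101 under TRF and 0.995 under AL), while DESeq2 called it under TRF (log2 -4.13, adjusted p 0.00536).

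**Figure D1:**
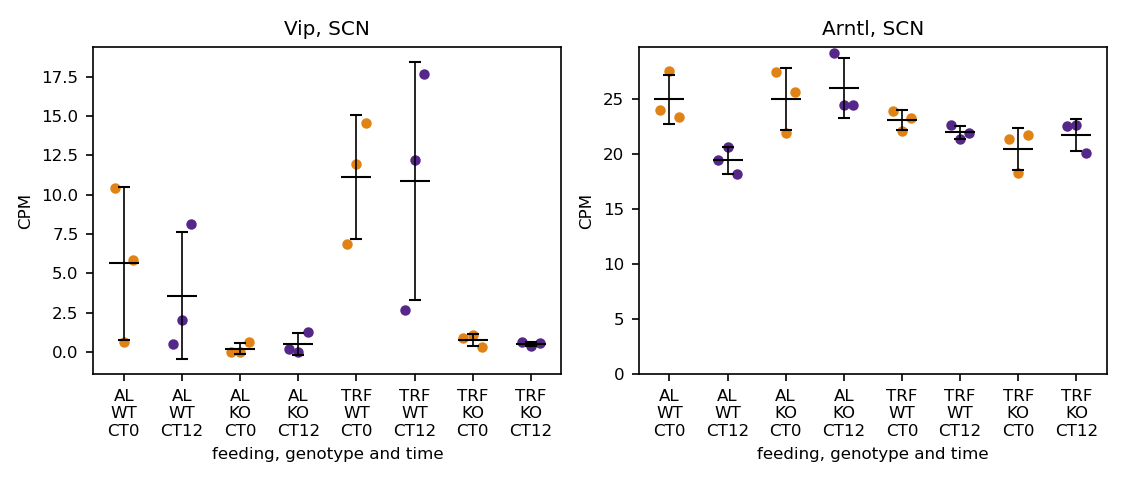
Vip and Arntl in each SCN library, in CPM, by feeding, genotype and time, with the mean and SD of each group of 3. The 12 KO libraries lie between 0 and 1.28 CPM of Vip, and the 12 WT libraries between 0.504 and 17.7.

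Outside the brain, Arntl differed between genotypes in some combinations of time and feeding, none of them with an exact p under 0.05. At CT12 under AL, liver Arntl was 28.7 ± 3.34 CPM in KO and 3.42 ± 0.0660 in WT, and heart Arntl 11.4 ± 2.35 and 4.57 ± 3.26 (n = 3 each; exact permutation p 0.1 in both, the smallest that 3 against 3 can give). At CT0 under AL, liver Arntl was 38.2 ± 2.39 in KO and 29.8 ± 1.96 in WT, and heart Arntl 22.9 ± 3.24 and 26.9 ± 2.06, lower in KO, with the same exact p. At CT0 under TRF, heart Arntl was 3.17 ± 1.92 in KO (n = 4) and 10.7 ± 1.74 in WT (n = 3; exact permutation p 0.0571), and liver Arntl 1.34 ± 0.398 and 1.97 ± 0.424 (p 0.114). At CT12 under TRF, p was 0.514 in liver and 0.8 in heart. Over the 4 combinations, the log2 difference of liver Arntl was 0.72 (permutation p 0.0496, 0.0991 adjusted) and that of heart Arntl -0.11 (p 0.723).

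**Figure D2:**
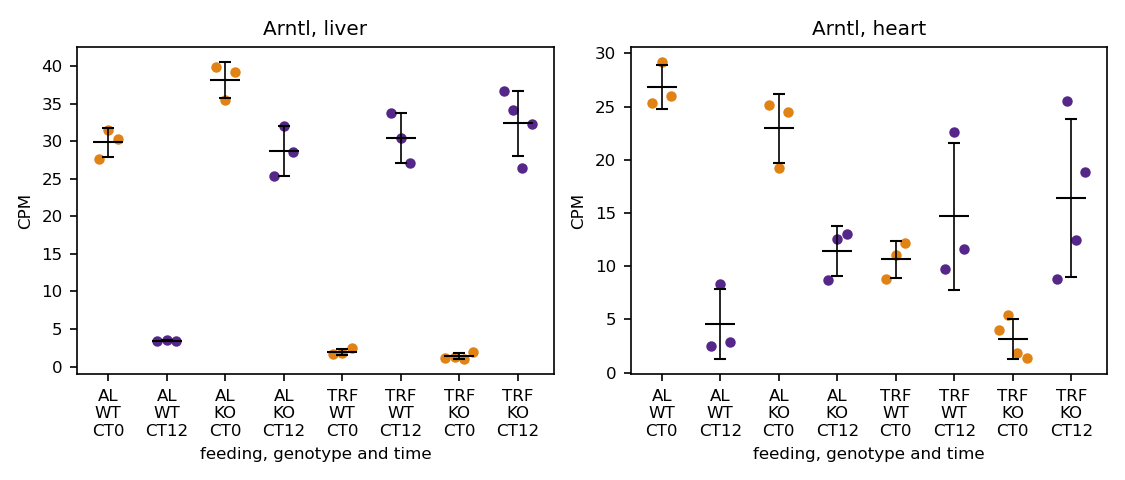
Arntl in each liver and heart library, in CPM, by feeding, genotype and time, with the mean and SD of each group. In liver, AL WT averages 3.42 at CT12 and 29.8 at CT0, and TRF WT 30.4 and 1.97.

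In livers of AL WT mice, clock genes set CT12 apart from CT0. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203 in GRCm38) stood at 48.9 ± 5.98 CPM at CT12 and 0.601 ± 0.308 at CT0 (n = 3 each; log2 6.34 ± 0.79, edgeR adjusted p 2.93e-05). Ciart rose from 0.724 ± 0.190 to 22.8 ± 1.70, Per3 from 2.54 ± 0.379 to 51.1 ± 9.29 and Nr1d2 from 6.16 ± 0.591 to 54.8 ± 11.3. Arntl fell from 29.8 ± 1.96 to 3.42 ± 0.0660 (log2 -3.12 ± 0.16, edgeR adjusted p 4.87e-12) and Npas2 from 13.8 ± 5.93 to 0.102 ± 0.0787. Of 19 core clock genes, 9 rose and 4 fell (11 and 4 adjusted over the list alone), and 6 were not called. Beyond the clock, Lpin1 rose from 50.6 ± 16.3 to 927 ± 82.3 CPM, while Elovl3 fell from 837 ± 15.1 to 48.2 ± 2.87, Cdkn1a from 36.8 ± 0.944 to 2.99 ± 1.01 and Pitx3 from 28.9 ± 2.58 to 1.49 ± 0.135. Of the cholesterol synthesis genes, 13 of 22 (16 adjusted over the list alone) fell and none rose, among them Hmgcs1, from 322 ± 38.9 to 68.7 ± 14.5. Gluconeogenesis genes rose, 4 of 14 (4 adjusted over the list alone), and red cell genes fell, 4 of 5 (4 adjusted over the list alone). None of these lists, nor the core clock list, kept its call without the 3-digit AL libraries (fry adjusted p 0.0696 to 0.206).

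Across the 14397 genes tested in liver, 1294 differed between CT12 and CT0 in AL WT, 640 higher and 654 lower at CT12. In liver and heart, the 3-digit AL libraries often lay between the other libraries of their groups, with the middle value in 40.3 to 60.5% of genes. Without them, 356 genes were called, 351 of them among the 1294. Leaving out 1 library gave 809 without 39, 850 without AL_WT_CT0_401, 802 without 47 and 740 without AL_WT_CT12_404.

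In AL KO livers, Dbp, Nr1d2 and Elovl3 lay at both times between their WT levels at CT0 and CT12. Dbp was 7.91 ± 5.46 CPM at CT12 and 2.22 ± 1.16 at CT0, Nr1d2 16.7 ± 5.83 and 15.3 ± 4.20, and Elovl3 465 ± 53.8 and 684 ± 29.2 (n = 3 each). Clic3, at 21.2 ± 4.12 in AL WT at CT0, was at 1.84 ± 0.204 in AL KO. Only Ppp1r3b (log2 1.34 ± 0.22) and Fam102a (0.89 ± 0.14) differed between CT12 and CT0 in edgeR, both higher at CT12, out of 821 genes with an unadjusted p under 0.05. DESeq2 called 31 and edgeR on the 2 compared groups alone 253, each count including both genes. Leaving out 1 library ended the calls of Ppp1r3b (56, AL_KO_CT0_407, 65, 66 or AL_KO_CT12_410; p 0.0505 to 0.271) and Fam102a (56, AL_KO_CT0_407 or AL_KO_CT12_410; p 0.119 to 0.271) in edgeR. Ppp1r3b did not pass without a filter on low counts (p 0.0615), and neither gene did without the 3-digit AL libraries (log2 1.32 and 0.84, p 1 for both). The count was 0 without 56, 10 without 57, 0 without AL_KO_CT0_407, 1 without 65, 5 without 66 and 0 without AL_KO_CT12_410. The time difference itself differed between genotypes for 225 genes, 146 with a more positive and 79 with a more negative difference in KO. They included Npas2 (interaction log2 5.61 ± 0.97), Arntl (2.71 ± 0.21), Clic3 (4.63 ± 0.51), Cdkn1a (4.12 ± 0.68), Lpin1 (-3.92 ± 0.77) and Nr1d2 (-3.03 ± 0.62), with edgeR adjusted p of at most 0.0123. That count was 26 without the 3-digit AL libraries, 136 without AL_WT_CT12_404, 135 without 57, 140 without AL_KO_CT0_407 and 134 without AL_KO_CT12_410, and 339 with DESeq2, 562 from the 4 groups alone and 479 with a term for the 3-digit AL libraries. Of these 6 genes, Arntl and Clic3 alone passed without the 3-digit AL libraries, which leaves 2 libraries per AL group. The others lost their calls at log2 6.53 for Npas2 (p 0.0749), 4.06 for Cdkn1a (p 0.148), -3.95 for Lpin1 (p 0.252) and -2.82 for Nr1d2 (p 0.356).

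Averaged over both times, cholesterol synthesis and cold-inducible genes were higher in AL KO than AL WT livers. Of the cholesterol synthesis genes, 18 of 22 (19 adjusted over the list alone) were higher and none lower (fry adjusted p 1.05e-04). Fdft1 stood at 303 ± 39.8 CPM in KO and 110.5 ± 1.96 in WT at CT12, and at 361 ± 62.1 and 222 ± 10.0 at CT0 (log2 1.08 ± 0.13, edgeR adjusted p 4.76e-06). Cirbp (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786 in GRCm38) was 36.5 ± 1.73 in KO and 18.6 ± 1.29 in WT at CT12 (log2 0.88 ± 0.14 over both times), with 4 of 5 (4 adjusted over the list alone) of the cold-inducible list higher. Follistatin (Fst) was higher at log2 3.16 ± 0.39, Chrna4 at 3.15 ± 0.58 and Tff3 at 3.01 ± 0.48. Alas1 was lower, at 251 ± 46.0 CPM in KO and 2148 ± 117 in WT at CT12, as were Cyp3a11 (log2 -2.08 ± 0.18), Hspa1b (-2.70 ± 0.52) and Mup17 (-3.19 ± 0.66); reads of Hspa1b and of the Mup and Cyp3a genes can be shared with near-identical copies. Of the immediate early genes, 7 of 9 (8 adjusted over the list alone) were higher, with Fos at 166 ± 103 in KO and 8.72 ± 8.78 in WT at CT0. In all, 2954 genes differed (1478 higher, 1476 lower in KO). Without the 3-digit AL libraries the count was 1134, the cholesterol list kept its call (adjusted p 0.00693) and the immediate early list lost its call (0.054).

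Under TRF, the liver clock genes of both genotypes ran opposite to those of AL WT. Dbp was 1.71 ± 1.43 CPM at CT12 and 143 ± 22.2 at CT0 in WT (n = 3; log2 -6.37 ± 0.70, edgeR adjusted p 4.12e-06), and 3.47 ± 3.56 and 164 ± 22.0 in KO (n = 4; log2 -5.57 ± 0.57, adjusted p 1.06e-06). Arntl rose to 30.4 ± 3.36 from 1.97 ± 0.424 in WT and to 32.4 ± 4.34 from 1.34 ± 0.398 in KO. Npas2 rose to 14.1 ± 3.19 from 0.465 ± 0.157 in WT and to 11.5 ± 5.97 from 0.0771 ± 0.0240 in KO. Cdkn1a reached 80.0 ± 17.5 at CT12 in WT and 24.2 ± 14.9 in KO, from 0.996 ± 0.130 and 0.883 ± 0.547. Tubb2a rose from 12.9 ± 2.83 to 377 ± 99.9 in WT, while Nr1d1 fell from 64.0 ± 3.86 to 3.88 ± 1.79 and Ppp1r3g from 67.0 ± 39.3 to 2.43 ± 2.69. In KO, 18 of 22 (19 adjusted over the list alone) cholesterol synthesis genes rose (fry adjusted p 1.47e-04), with Sqle at 207 ± 49.1 at CT12 and 56.0 ± 16.1 at CT0. In WT, 11 of 22 (16 adjusted over the list alone) rose and 1 fell (adjusted p 0.0188, and 0.0696 without the 3-digit AL libraries). Xenobiotic genes fell in KO (10 of 18, and 10 adjusted over the list alone), Por among them (log2 -2.17 ± 0.35). Genes of the other cell types of the liver rose in WT (6 of 16, and 6 adjusted over the list alone) and KO (4 of 16, and 6 adjusted over the list alone).

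**Figure D3:**
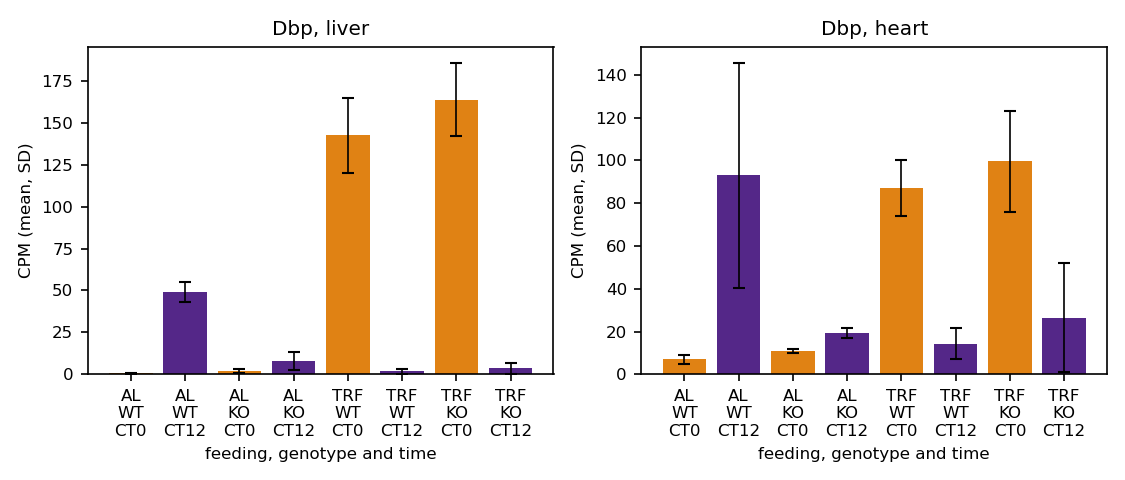
Dbp in liver and heart, in CPM, as the mean of each group with its SD (3 libraries, or 4 in TRF KO). The liver mean is highest in TRF KO at CT0, at 164, and lowest in AL WT at CT0, at 0.601.

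CT12 and CT0 differed for 3323 genes in TRF WT livers (1588 higher, 1735 lower at CT12) and 3167 in TRF KO livers (1515 and 1652). The 2 sets share no library, and 1825 genes were called in the same direction in both, where independent lists of these sizes would share 366, and 11 in opposite directions. Between AL WT and TRF WT, 680 genes were called in opposite directions, against 149 for independent lists, and 31 in the same direction. The TRF WT count was 1622 from its 2 groups alone, and 2215 without 1 and 2083 without 12. In TRF KO it was 1934 from its 2 groups alone and 1973 without 55 and 64, whose numbers lie among those of the AL KO animals.

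Between genotypes under TRF, Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964 in GRCm38) showed the largest fall among genes that met the naming rule: 279.7 ± 109 CPM in KO (n = 4) and 2775 ± 632 in WT (n = 3) at CT0, and 473 ± 95.6 and 3046 ± 347 at CT12 (log2 -3.00 ± 0.17, edgeR adjusted p 1.26e-10). Csad was lower as well, at log2 -2.33 ± 0.31, as were Gsta1 (-2.61 ± 0.26) and Pde4a (-1.16 ± 0.13). Gpx6 was higher (3.89 ± 0.39), as were Nipal1 (1.89 ± 0.41) and Cyp2c54 (0.99 ± 0.16). Cholesterol synthesis genes were again higher in KO, 18 of 22 (19 adjusted over the list alone), at a fry adjusted p of 8.69e-04, with Msmo1 at log2 1.08 ± 0.17. Cirbp stood at 62.2 ± 5.67 CPM in KO and 31.1 ± 1.57 in WT at CT0, and 3 of 5 (4 adjusted over the list alone) cold-inducible genes were higher. Heat shock genes were lower, 5 of 17 (6 adjusted over the list alone), a list call that ended without the 3-digit AL libraries, which share the estimate of spread (fry adjusted p 0.0286 and 0.0851). No core clock gene differed. In all, 1494 genes differed (766 higher, 728 lower in KO), 588 from the 4 groups alone, 992 without a filter on low counts, and 701 without 3 and 922 without 12. The time difference itself differed between genotypes for 8 genes, among them Tkfc (log2 -1.19 ± 0.20). Leaving out 1 library ended the edgeR call of Tkfc (1, 20, 55 or 29; p 0.0614 to 0.0809), as did fitting the 4 groups alone (p 0.453) and leaving out 55 and 64 (p 0.101). DESeq2 called 63 and edgeR on the 4 groups alone 0, 14 without a filter and 4 without 55 and 64. With 1 library left out, the count was 1 without 1, 5 without 2, 5 without 3, 64 without 11, 3 without 12, 5 without 73, 0 without 20, 5 without 21, 0 without 55, 24 without 28, 0 without 29, 19 without 30 and 5 without 64.

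The time differences of liver clock genes depended on feeding in both genotypes, although under AL no clock gene was called between times in KO. In WT, the difference between the TRF and AL time effects was -12.71 ± 1.05 on the log2 scale for Dbp, 7.06 ± 0.24 for Arntl and 11.93 ± 0.98 for Npas2. In KO it was -7.40 ± 0.87 for Dbp, 5.00 ± 0.21 for Arntl and 8.47 ± 0.87 for Npas2, with edgeR adjusted p of at most 1.96e-05 for all 6 values. 3602 genes passed in WT and 1604 in KO, and 2150 and 565 without the 3-digit AL libraries; the KO count was 1047 without 65. Cholesterol synthesis genes moved up with TRF in both (16 of 22 in WT, 14 in KO; 18 and 17 adjusted over the list alone). Averaged over genotypes and times, Mt1 was higher in TRF (log2 3.48 ± 0.55), as were Orm2 (1.97 ± 0.34), Cyp4a10 (1.74 ± 0.22) and Cyp4a14 (3.08 ± 0.40). All 10 genes of the male-biased list were lower, with either adjustment, Elovl3 by log2 -1.48 ± 0.20 (fry adjusted p 1.01e-04), of the female-biased list 3 of 5 (5 adjusted over the list alone) were higher, and 16 of 22 (18 adjusted over the list alone) cholesterol synthesis genes were lower. Altogether 2854 genes differed between TRF and AL (1565 higher, 1289 lower), and 835 without the 3-digit AL libraries.

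Whether feeding changed the genotype's effect on the time difference was tested by the interaction of all 3 factors. It passed for 102 liver genes, among them Clic3 (log2 -5.98 ± 0.77), Cdkn1a (-5.70 ± 1.10), Tubb2a (-4.30 ± 0.49), Nrep (3.16 ± 0.47) and Arntl (-2.06 ± 0.32). Leaving out 1 library ended the edgeR call of Cdkn1a (21; p 0.0569), which did not pass without the 3-digit AL libraries either (log2 -5.64, p 0.222). In Arntl the AL genotypes differed by 2.71 in their time effects and the TRF genotypes by 0.65. The count was 248 with DESeq2, 16 without the 3-digit AL libraries, and 157 without 10, 182 without 11, 67 without 39, 60 without AL_WT_CT0_401, 56 without AL_WT_CT12_404, 66 without 57, 59 without AL_KO_CT0_407, 64 without 66 and 57 without AL_KO_CT12_410.

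In AL WT hearts, the clock genes differed between times in the same sense as in liver. Arntl fell from 26.9 ± 2.06 CPM at CT0 to 4.57 ± 3.26 at CT12 (n = 3 each; log2 -2.60 ± 0.46, edgeR adjusted p 1.26e-04), and Nfil3 from 29.9 ± 0.696 to 8.85 ± 0.628. Dbp rose from 6.99 ± 1.98 to 93.1 ± 52.7 and Per3 from 14.8 ± 1.71 to 73.6 ± 17.8. Of 19 core clock genes, 12 rose and 6 fell (13 and 6 adjusted over the list alone). Fatty acid genes fell, 14 of 19 (15 adjusted over the list alone) with none rising (fry adjusted p 4.13e-04; median log2 -0.45, beside -0.32 for all genes to which the brain transcripts described next would add little). Library 48, 1 of the 3 at CT12, stood apart in its counts, with 34.2% in mitochondrial genes and 36.7% in its 10 most abundant genes, where the other hearts had 7.76 to 13.6% and 16.6 to 21.4%. Without it, the core clock and fatty acid lists kept their calls (fry adjusted p 0.00206 and 0.00134), as did in edgeR each gene named in this paragraph. Angptl4 fell from 30.3 ± 6.51 to 5.21 ± 1.18 and Pdk4 from 608 ± 63.4 to 275 ± 24.0. Spon2 fell from 17.9 ± 6.26 to 1.92 ± 0.564, Tmem171 from 11.4 ± 0.167 to 1.91 ± 0.695 and Colq from 21.6 ± 1.65 to 4.67 ± 0.474.

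The 3 AL WT CT12 heart libraries also held transcripts that were scarce in other hearts. Slc17a6, a gene of glutamatergic neurons, averaged 22.0 ± 17.9 CPM there and 0 in all 3 AL WT CT0 hearts. The 464 genes abundant in SCN (at least 50 CPM) and near absent from the other hearts (at most 1 CPM) stood at a median of 8.14 to 19.7% of their SCN level, and in no other heart library above 0.272%. Atrial genes were high in the same libraries: Myl7 (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782 in GRCm38) averaged 756 ± 543 against 0.892 ± 0.368 at CT0, and 722 ± 447 in AL KO at CT0. In this setting 6600 of 16397 genes differed between times (3784 higher, 2816 lower at CT12). Among the 4999 genes to which such a share of SCN RNA would add at most 10%, 2214 differed, 165 higher and 2049 lower. The median log2 change of those genes was -0.32, and 225 of the calls changed more than 2-fold (127 lower, 98 higher). From the 2 groups alone, 3292 of all genes were called (2637 higher, 655 lower), and 5631 without library 48.

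**Figure D4:**
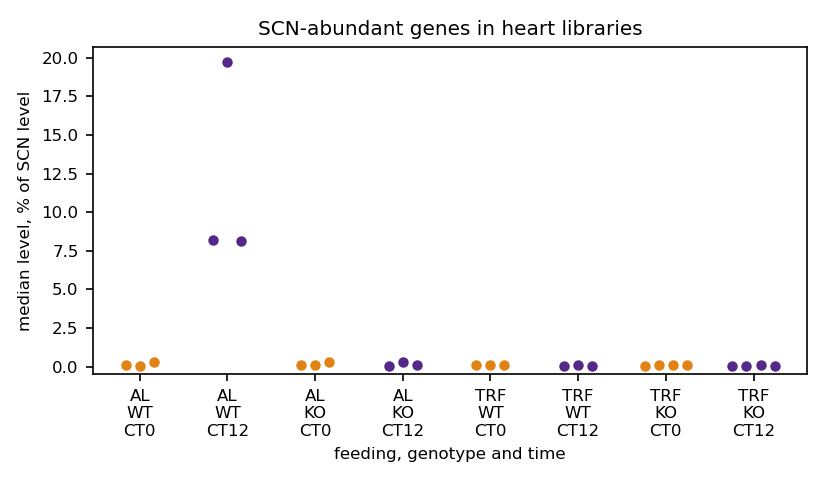
Median level of the 464 SCN-abundant genes in each heart library, as a percentage of their SCN level, by feeding, genotype and time. The 3 AL WT CT12 libraries lie between 8.14 and 19.7%, and the others at or under 0.272%.

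In AL KO hearts, Arntl was 11.4 ± 2.35 CPM at CT12 and 22.9 ± 3.24 at CT0, and Dbp 19.3 ± 2.27 and 10.9 ± 0.884. Neither passed in edgeR. The genes that did pass, 28 in all (3 higher, 25 lower at CT12), included Irx2 (log2 0.87 ± 0.17) among the rises and Fgf12 (-2.85 ± 0.44) among the falls. Leaving out 1 library ended the edgeR calls of Irx2 (56, 57, AL_KO_CT0_407, 65 or AL_KO_CT12_410; p 0.0864 to 0.134) and Fgf12 (57 or AL_KO_CT12_410; p 0.053 to 0.102), and fitting the 2 groups alone that of Fgf12 (p 0.226). Fgf12 and the atrial genes were raised in the same AL libraries, and 6 of 6 atrial genes were lower at CT12 when adjusted over the list alone, with 0 over all genes. DESeq2 called 107, the 2 groups alone gave 121, no filter on low counts 17, and leaving out 1 library 4 without 57, 17 without AL_KO_CT0_407, 3 without 65, 56 without 66 and 0 without AL_KO_CT12_410. The genotypes' time differences differed for 4683 genes, and for 2901 with a term for the 3-digit AL libraries. Angptl4 (interaction log2 3.38 ± 0.62), Tmem171 (2.38 ± 0.36) and Nfil3 (1.58 ± 0.21) moved up in KO relative to WT, and Hlf (-1.57 ± 0.29), Bhlhe40 (-1.25 ± 0.27) and Dbp (-2.92 ± 0.85) down. Without the 3-digit AL libraries, Dbp lost its call at a similar size (log2 -2.82, edgeR adjusted p 0.0997). Of the fatty acid genes, 15 of 19 (15 adjusted over the list alone) moved up (fry adjusted p 5.98e-04; median log2 0.57). Among genes that SCN RNA would raise by at most 10%, 1652 passed, and the median log2 over all such genes was 0.37.

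Endoplasmic reticulum stress genes were higher in AL KO than AL WT hearts over both times: 11 of 18 (11 adjusted over the list alone), none lower (fry adjusted p 4.13e-04; median log2 0.34, beside 0.14 for all genes that SCN RNA would raise little). Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547 in GRCm38) stood at 849.9 ± 47.6 CPM in KO and 536 ± 68.4 in WT at CT0, and 606 ± 62.3 and 397 ± 13.1 at CT12 (n = 3 each; log2 0.64 ± 0.08, edgeR adjusted p 1.00e-05). Gnb3 was higher in KO (log2 1.22 ± 0.12), as were Nppb (1.31 ± 0.18) and Myom2 (0.91 ± 0.09), and of the glucose genes 8 of 15 (9 adjusted over the list alone), with a median log2 of 0.24. The largest falls, Tagln3 (log2 -2.66 ± 0.26), Pde1b (-1.95 ± 0.21) and Camk2b (-1.56 ± 0.15), were genes with high levels in the AL WT CT12 libraries that held brain transcripts, such as Camk2b at 108 ± 55.6 there and 20.0 ± 2.12 at CT0. In total, 3048 genes differed (1040 higher, 2008 lower in KO). The count was 730 (710 and 20) among genes that SCN RNA would raise by at most 10%, 1901 without the 3-digit AL libraries, and 1686 with a term for them.

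Under TRF, hearts of both genotypes differed between times in clock and metabolic genes, the clock genes named here in the opposite sense to AL WT. In WT, Dbp fell from 87.2 ± 13.0 CPM at CT0 to 14.4 ± 7.35 at CT12 (n = 3 each; log2 -2.61 ± 0.58, edgeR adjusted p 0.0152), Pdk4 from 1114 ± 153 to 328 ± 133 and Ucp3 from 134 ± 22.1 to 40.8 ± 16.8. Tfrc rose from 16.5 ± 4.48 to 72.7 ± 15.1, and Nfil3 from 9.81 ± 0.734 to 32.5 ± 3.88. Hspa1b rose from 2.08 ± 0.583 to 18.1 ± 7.00, with 7 of 17 (9 adjusted over the list alone) heat shock genes rising, none falling (fry adjusted p 1.35e-04), and 2 of 5 (3 adjusted over the list alone) cold-inducible genes falling, Cirbp from 90.1 ± 10.5 to 47.0 ± 4.22. In KO (n = 4), Arntl rose from 3.17 ± 1.92 to 16.4 ± 7.39 (log2 2.37 ± 0.42, edgeR adjusted p 0.00346), Nfil3 from 11.2 ± 1.47 to 24.5 ± 5.86 and Slc41a3 from 39.7 ± 9.59 to 138 ± 35.1, while Ucp3 fell from 136 ± 42.4 to 49.1 ± 1.55 and Dbp from 99.7 ± 23.6 to 26.6 ± 25.4. Leaving out 1 library ended the edgeR calls of Dbp (11 or 12; p 0.053 to 0.0754) in WT and Dbp (73, 21, 55, 28, 29 or 64; p 0.0566 to 0.111) in KO. Fitting the 2 compared groups alone ended those of Pdk4 (p 0.0749) and Ucp3 (p 0.076) in WT and of Arntl (p 0.0697) and Dbp (p 0.172) in KO. Dbp in KO did not pass without a filter (p 0.0746) or without 55 and 64 (p 0.161) either. Endoplasmic reticulum stress genes rose in WT (6 of 18, and 11 adjusted over the list alone) and KO (6 of 18, and 12 adjusted over the list alone).

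In total 718 genes differed between times in TRF WT hearts (363 higher, 355 lower at CT12) and 528 in TRF KO hearts (285 and 243). These sets share no library. They held 221 genes called in the same direction, where independent lists would share 11.6, and 0 called in opposite directions. Between AL WT and TRF WT hearts, 265 were called in opposite directions, against 144 for independent lists, and 57 in the same. The TRF WT count was 1278 from its 2 groups alone, 434 without a filter on low counts, and 336 without 1, 381 without 2, 251 without 3, 323 without 10 and 248 without 12. The TRF KO count was 820 with DESeq2, 329 without a filter, 113 without 55 and 64, and 247 without 21, 312 without 55, 291 without 28 and 255 without 64. The 3 TRF WT CT0 hearts also held liver transcripts, looked at after the data were seen. Alb averaged 158 ± 19.6 CPM there and 2.41 ± 1.10 at CT12. The 50 genes abundant in liver (at least 1000 CPM) and near absent from hearts with little Alb stood at a median of 0.178 to 0.228% of their liver level at CT0 and at most 0.00566% at CT12. Single libraries of other groups came near this, such as library 20 of TRF KO CT0 (0.187%), up to 0.189% in AL KO CT12. Of the 718 calls in TRF WT, 692 (363 higher, 329 lower) were of genes to which the highest share would add at most 10%.

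Heat shock genes were lower and cold-inducible genes higher in TRF KO than TRF WT hearts. Hsph1 stood at 42.4 ± 7.41 CPM in KO (n = 4) and 104 ± 49.9 in WT (n = 3) at CT12, and 31.9 ± 3.40 and 66.9 ± 11.1 at CT0 (log2 -1.18 ± 0.18, edgeR adjusted p 0.00228). Of the heat shock list, 9 of 17 (16 adjusted over the list alone) were lower (fry adjusted p 9.35e-05). Cirbp was 83.8 ± 10.8 in KO and 47.0 ± 4.22 in WT at CT12, with 2 of 5 (3 adjusted over the list alone) cold-inducible genes higher (fry adjusted p 4.60e-04). Acta1 was lower (log2 -1.44 ± 0.28), as was Cdkn1a (-1.02 ± 0.16), and Irx2 was higher (0.74 ± 0.12). In sum 453 genes differed (207 higher, 246 lower in KO). The count was 842 with DESeq2, 1126 from the 4 groups alone, 241 without a filter, and 137 without 1, 292 without 2, 243 without 3, 299 without 11, 291 without 12, 291 without 73, 282 without 20 and 232 without 30. Of the 453, 448 were genes to which the liver RNA of the TRF WT CT0 hearts would add at most 10%. No gene passed for a difference between the genotypes' time effects in edgeR; 932 had an unadjusted p under 0.05, DESeq2 called 32, and leaving out library 11 gave 25.

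Feeding shifted the time differences of heart genes in both genotypes. The TRF minus AL difference of time effects was -6.34 ± 0.85 for Dbp, 3.06 ± 0.63 for Arntl and 3.48 ± 0.21 for Nfil3 in WT, and 3.37 ± 0.60 for Arntl, 2.46 ± 0.31 for Slc41a3 and -2.30 ± 0.34 for Ucp3 in KO, each with an edgeR adjusted p of at most 0.00634. It passed for 4899 genes in WT, with 1467 among genes that SCN RNA would raise by at most 10%, and for 271 in KO. The KO count was 502 with DESeq2, 510 from the 4 groups alone, 119 without 55 and 64, and 153 without 55, 135 without 56, 129 without 57, 153 without AL_KO_CT0_407, 83 without 65 and 111 without AL_KO_CT12_410. Endoplasmic reticulum stress genes moved up in both (9 and 10 of 18; 11 and 12 adjusted over the list alone), and heat shock genes in WT (12 of 17, 12 over the list alone). In WT the median log2 was 0.57 for the former and 0.67 for the latter, beside 0.32 for all genes that SCN RNA would raise little. Averaged over genotypes and times, 11 of 19 (11 adjusted over the list alone) fatty acid genes were higher in TRF (fry adjusted p 4.13e-04; median log2 0.25, beside 0.08 for all genes that SCN RNA would raise little), with Cpt1a at log2 0.45 ± 0.06. In total 3586 genes differed by feeding (1325 higher, 2261 lower in TRF). Among genes that SCN RNA would raise little, 922 did, with the opposite balance (796 higher, 126 lower). The interaction of all 3 factors passed for 2042 heart genes, Angptl4 (log2 -3.88 ± 0.84), Tmem171 (-2.35 ± 0.49), Klf10 (-2.32 ± 0.51) and Nfil3 (-2.18 ± 0.29) among them, and for 410 of the genes that SCN RNA would raise little.

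In the SCN, few genes were called between times. In AL WT, Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665 in GRCm38) rose from 64.7 ± 5.83 CPM at CT0 to 90.5 ± 4.70 at CT12 (n = 3 each; log2 0.48 ± 0.08, edgeR adjusted p 0.0255). Slc2a1 rose from 96.1 ± 9.83 to 147 ± 5.73, Ahnak from 24.2 ± 1.09 to 39.5 ± 3.23, Nfkbia from 17.1 ± 0.998 to 28.8 ± 2.88 and Galnt15 from 4.19 ± 0.776 to 7.69 ± 0.526, which completed the 5 calls of 18133 genes. Adjusted over the list alone, 7 of 19 core clock genes rose and 1 fell, against 1 and 0 over all genes (fry adjusted p 0.028). In TRF WT, Ahnak rose from 26.2 ± 2.02 to 45.5 ± 5.30 and Slc38a2 from 107 ± 8.76 to 164 ± 22.4, while Cirbp fell from 169.9 ± 16.8 to 103 ± 15.6. All 17 heat shock genes had positive values there, 11 called over the list alone and 0 over all genes (fry adjusted p 0.028). DESeq2 called 20 genes in AL WT and 63 in TRF WT, and edgeR without a filter 8 and 7. With 1 library left out, the count was 3 without 38, 1 without 39, 1 without 47, 0 without 48, 3 without AL_WT_CT0_401 and 3 without AL_WT_CT12_404 in AL WT, and 0 without 2, 1 without 3, 5 without 10 and 1 without 12 in TRF WT. Such a removal ended the edgeR calls of Per3 (38, 47, 48 or AL_WT_CT0_401; p 0.107 to 0.26), Slc2a1 (39 or 48; p 0.081 to 0.0858), Ahnak (38, 39, 47, 48 or AL_WT_CT0_401; p 0.0624 to 0.234), Nfkbia (38, 39, 47, 48, AL_WT_CT0_401 or AL_WT_CT12_404; p 0.0683 to 0.322) and Galnt15 (38, 39, 47, 48 or AL_WT_CT12_404; p 0.0683 to 0.29) in AL WT, and of Ahnak (2; p 0.105), Slc38a2 (1, 2, 3, 10 or 12; p 0.057 to 0.418) and Cirbp (2, 3, 10 or 12; p 0.0803 to 0.418) in TRF WT. With the 2 compared groups alone in the fit, none of these 8 calls was kept (p 0.0978 to 0.382). Cirbp in TRF WT did not pass without a filter (p 0.0506), nor did it or Slc38a2 without libraries 1 and 10 (p 0.105 and 0.264). In AL KO and TRF KO, edgeR called 0 genes, with 369 and 1139 at an unadjusted p under 0.05, and DESeq2 called 0 and 0.

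Between genotypes, Cnih3 was the single SCN gene that passed, higher in TRF KO (log2 0.72 ± 0.11, edgeR adjusted p 0.0226; named after its value was seen). With 1 library left out, the count was 0 without 1, 2 without 2, 3 without 11, 3 without 12, 0 without 20, 4 without 55, 0 without 28, 0 without 29 and 0 without 30, and the call of Cnih3 (1, 3, 20, 28, 29 or 30; p 0.0535 to 0.112) ended, as it did with the 4 groups alone (p 0.0648) and without 1 and 10 (p 0.0595). DESeq2 called 81 in TRF and 0 in AL, where edgeR called 0 (848 at an unadjusted p under 0.05). For the difference between the genotypes' time effects, edgeR called 0 in AL (456 unadjusted; DESeq2 2) and 0 in TRF (793; DESeq2 13). For the feeding by time difference it called 0 in WT (1220; DESeq2 23) and 0 in KO (826; DESeq2 0), and for the interaction of all 3 factors 0 (444; DESeq2 0). In simulated SCN data, 3-fold changes were recovered for 96% of genes between genotypes under AL and 98% between times in AL WT. The share was 80% for genotype by time under AL. At 1.5-fold, shares were 76, 54 and 42%. These shares are over genes drawn at random above a mean of 1 CPM, independently and without variation shared across genes. SCN libraries differed in nearby tissue (lateral hypothalamic Hcrt, 0.177 to 574 CPM), which can hide changes in SCN cells. With fewer true changes than the 200 simulated, a stricter adjusted threshold would lower the shares. Genes as variable as Vip can be missed. Vip was lower in AL KO by log2 -2.71 at CT0 and -1.73 at CT12 (log2 of CPM plus 0.5) and was not called by edgeR.

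TRF and AL libraries of the SCN differed in genes of other brain regions. Pomc averaged 13.5 CPM in TRF and 60.3 in AL over 12 libraries each (log2 -2.73 ± 0.53, edgeR adjusted p 0.00519). Of 6 genes of other hypothalamic regions, Pomc included, all were lower in TRF, and 4 of 6 striatal genes were higher. Among the latter was Ppp1r1b, at 185 in TRF and 48.3 in AL. These 12 genes were chosen after the data were seen, and leaving out 1 library ended the edgeR call of Ppp1r1b (1 or 10; p 0.0531 to 0.0602), as did leaving out both (p 0.116). Microglial genes were higher in TRF, 7 of 8 (7 adjusted over the list alone), with Csf1r at log2 0.32 ± 0.07. Of the core clock genes, Cry2 was higher (0.14 ± 0.04) and Nfil3 lower (-0.32 ± 0.09) in TRF. Without libraries 1 and 10, Nfil3 stayed lower but lost its call (log2 -0.25, edgeR adjusted p 0.0695). In total 2956 genes differed (1624 higher, 1332 lower in TRF). The count was 1554 without TRF WT libraries 1 and 10, 1953 without 21 and 1839 without 39. It was 40 (40 higher, 0 lower in TRF) with a term for the main axis of variation between libraries of the same group, under which no gene named here passed.

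Liver and heart were set against each other by testing whether their time effects differed. In AL WT, Npas2 fell more in liver (heart minus liver log2 5.64 ± 0.98, edgeR adjusted p 5.10e-05), while Usp2 (-3.19 ± 0.57) and Por (-2.07 ± 0.42) rose more in liver. In TRF WT and TRF KO, Dbp fell more in liver (log2 3.73 ± 0.87 and 3.67 ± 0.71) and Npas2 rose more in liver (-5.24 ± 0.77 and -5.81 ± 0.91), as did Arntl (-3.50 ± 0.52 and -2.22 ± 0.49). The tissues' time effects differed for 3102 of 17656 genes in AL WT, 2016 in TRF WT and 1737 in TRF KO. In AL KO Fras1 alone passed (log2 -3.49 ± 0.48), DESeq2 called 19, and leaving out 1 library gave 2 without liver library 66, 4 without heart library 56, 4 without heart library AL_KO_CT0_407, 3 without heart library 66 and 6 without liver library 57. Without the 3-digit AL libraries the AL WT count was 1858. Another scaling (RLE) moved the share of AL WT calls with a higher value in heart from 51.0% to 61.2%. In TRF WT the count was 1256 without a filter and 1296 without liver library 12, and in TRF KO 971 without 55 and 64. Among the largest differences of these 3 sets were transcripts of one tissue found in trace amounts in the other, such as brain and atrial genes in AL WT hearts.

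Of the gene list tests, 48 of 240 passed in liver, 46 of 192 in heart and 8 of 240 in SCN (fry, adjusted within a tissue). In liver, heat shock genes rose at CT12 in TRF WT (10 of 17, and 12 adjusted over the list alone) and TRF KO (8 of 17, and 9 adjusted over the list alone), and endoplasmic reticulum stress genes likewise (11 of 18, and 11 adjusted over the list alone, in WT; 9 of 18, and 13 adjusted over the list alone, in KO). Both lists were lower in TRF than AL (7 of 17 and 9 of 18 called; 10 and 12 adjusted over the list alone). Clock output genes passed as a rise in TRF WT, with 6 of 17 up and 4 down (median log2 -0.16, mean 0.33). Bile acid genes passed in TRF WT alone (3 of 11, and 5 adjusted over the list alone, lower at CT12). Fasting genes passed in TRF KO (7 of 20, and 9 adjusted over the list alone, lower at CT12) and by feeding (5 of 20, and 7 adjusted over the list alone, higher in TRF). Lipogenesis (lowest adjusted p 0.0594), acute phase (0.114), glucocorticoid target (0.104), immune cell (0.211) and sex marker genes (0.0891) passed in no liver comparison. Without the 3-digit AL libraries, 15 of the 48 liver calls were kept. They were cholesterol synthesis in 6 comparisons (the time effect of TRF KO, both genotype effects, both feeding by time differences and the feeding effect), cold-inducible genes in both genotype effects, genes of other liver cells in 3, the male-biased and female-biased lists by feeding, xenobiotic genes in TRF KO and clock output genes in TRF WT. Without TRF KO libraries 55 and 64, 43 were kept; heat shock, endoplasmic reticulum stress, fasting and gluconeogenesis genes in TRF KO and clock output genes in the TRF genotype by time difference were not.

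In heart, atrial genes passed in 7 comparisons, all of them with the AL WT CT12 or AL KO CT0 libraries that held these transcripts. Glucose genes fell in AL WT (10 of 15, and 10 adjusted over the list alone, with 3 rising), at a median log2 of -0.42 beside -0.32 for all genes that SCN RNA would raise little. Glucocorticoid targets were lower in TRF KO than TRF WT (1 of 13, and 2 adjusted over the list alone) and higher in TRF than AL (4 of 13, and 5 adjusted over the list alone), and cardiac stress genes were lower in TRF KO than TRF WT (3 of 14, and 6 adjusted over the list alone). Of the 46 heart calls, 17 ended without the 3-digit AL libraries and 10 without 55 and 64. The heat shock, cold-inducible, endoplasmic reticulum stress, fatty acid and glucose calls given above were kept in each alternative. Heat shock calls that ended in at least 1 were those of AL WT, TRF KO, TRF genotype by time, KO feeding by time and all 3 factors; cold-inducible calls, AL WT, feeding and all 3 factors; glucose calls, AL genotype by time and feeding. So did the atrial call of the AL genotype effect, the cardiac stress calls of AL KO and KO feeding by time, the endoplasmic reticulum stress call of AL KO and the core clock call of WT feeding by time. Of the glucocorticoid and cardiac stress calls given here, none of the 3 was kept in every alternative: both of the glucocorticoid list ended without the 3-digit AL libraries, and the cardiac stress call without 55 and 64 (fry adjusted p 0.0758, 0.0869 and 0.0631). Conduction (0.0835), clock output (0.0835), red cell (0.121), immune cell (0.165), immediate early (0.307), sex marker (0.393) and other-tissue genes (0.0599) did not pass in heart with all libraries. Without library 48 of AL WT CT12, conduction genes passed in 9 comparisons, other-tissue genes in 6 and clock output genes in 3, and the atrial genes lost their call for the AL genotype effect (fry adjusted p 0.11). In SCN, clock output genes passed in AL WT (3 of 17 higher at CT12 over the list alone, 0 over all genes) and moved down in KO in the AL genotype by time difference (1 over the list alone, 0 over all genes). Glucocorticoid targets passed in AL WT as well (6 of 13 higher over the list alone, 0 over all genes), and heat shock genes in the feeding by time difference of WT (15 of 17 over the list alone, 0 over all genes). Neuropeptides of nearby regions were lower in TRF than AL (4 of 10, and 4 adjusted over the list alone). SCN neuropeptide (0.197), SCN identity (0.441), GABA (0.113), calcium and CRE (0.262), astrocyte (0.125), oligodendrocyte (0.095), neuron (0.148) and vascular lists (0.418) did not pass, nor did cold-inducible (0.0501), endoplasmic reticulum stress (0.157), immediate early (0.193), immune cell (0.0942), red cell (0.258) or sex marker genes (0.37).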

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

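The tests of explanations below, the other splits of all liver results, and those of the time effects in heart and SCN and of the AL genotype comparisons in heart were chosen after the results they concern had been seen; the remaining splits were set before.

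In the TRF KO groups of liver and heart, the only ones with 4 libraries, single libraries stood apart from the others of their group by Dixon's test at its 95% critical value. In liver these were library 20 at CT0 for Npas2 (0.113 CPM, others 0.0602 to 0.0685), and library 30 at CT12 for Nr1d1 (68.2 CPM, others 2.76 to 6.57). The Npas2 values rest on a few reads per library at most, so that difference is within counting error. In heart they were library 21 at CT0 for Per2 (68.5 CPM, others 40.9 to 45.3) and for Ciart (25.7 CPM, others 7.64 to 9.09), and library 30 at CT12 for Nr1d1 (125 CPM, others 29.0 to 38.5). That is 5 of 76 groups of values tested, where chance gives about 1 in 20. Library 30 was high for Nr1d1 in both tissues. No explanation was tested.

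Effects that differed between groups by a test of the difference itself were, in liver, genotype by time (225 genes under AL, 8 under TRF), feeding by time (3602 in WT, 1604 in KO) and the interaction of all 3 factors (102). In heart they were genotype by time under AL (4683), feeding by time (4899 in WT, 271 in KO) and all 3 factors (2042). Liver and heart differed in their time effects for 3102 genes in AL WT, 1 in AL KO, 2016 in TRF WT and 1737 in TRF KO.

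Other splits of the same libraries into groups of the same sizes were fitted. Given for each result are how many splits called at least as many genes, the real split included, then the real count and the highest of the other splits. For the liver time effects, splits of 3 against 3 libraries number 10, too few for a share under 0.05, and the real count was 1294 for AL WT (highest other 0), 2 for AL KO (highest other 0) and 3323 for TRF WT (highest other 53). Chance can be excluded at a share under 0.05 for TRF KO, 1 of 35 (3167 real, highest other 362); AL genotype, 1 of 100 (2954 real, highest other 1043); TRF genotype, 1 of 100 (1494 real, highest other 479); WT feeding by time, 1 of 100 (3602 real, highest other 2466); KO feeding by time, 3 of 100 (1604 real, highest other 2103); feeding, 1 of 100 (2854 real, highest other 668); all 3 factors, 4 of 100 (102 real, highest other 576). It cannot be excluded for AL genotype by time, 5 of 100 (225 real, highest other 1043); TRF genotype by time, 23 of 100 (8 real, highest other 564). Splits that call several times the 225 and the 8 genes of the genotype by time differences point to a structure of the libraries. A split that mixes genotypes at 1 time turns the genotype effect itself into a difference of this kind. In liver and heart, a split that exchanges feeding at 1 time likewise turns the feeding effect into a feeding by time difference. The shares given for feeding by time therefore do not test that difference alone. For all 3 factors, the splits exchanged feeding within each genotype and time, and the source of the 576 calls was not tested.

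For the heart time effects, splits of 3 against 3 libraries number 10, too few for a share under 0.05, and the real count was 6600 for AL WT (highest other 1), 28 for AL KO (highest other 0) and 718 for TRF WT (highest other 1). Chance can be excluded at a share under 0.05 for TRF KO, 1 of 35 (528 real, highest other 18); AL genotype by time, 1 of 100 (4683 real, highest other 3708); TRF genotype, 1 of 100 (453 real, highest other 36); WT feeding by time, 1 of 100 (4899 real, highest other 3756); KO feeding by time, 3 of 100 (271 real, highest other 422); feeding, 1 of 100 (3586 real, highest other 2291); all 3 factors, 2 of 100 (2042 real, highest other 2643). It cannot be excluded for AL genotype, 8 of 100 (3048 real, highest other 3742). Beside a real count of 0 every split has at least as many, so the splits decide nothing for TRF genotype by time, 100 of 100 (0 real, highest other 260). The split with most genes for the AL genotype effect exchanged the genotypes of all 6 CT12 libraries, which turns the genotype by time difference into a genotype effect. The split with most genes for TRF genotype by time exchanged genotypes in 6 of the 7 CT12 libraries and so turned the genotype effect into that difference. Both point to a structure of the libraries that follows the real groups. The splits cannot tell an effect of genotype, feeding or time from the brain and atrial transcripts of the AL WT CT12 hearts. That limit holds for each comparison with this group, liver against heart in AL WT included.

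For the SCN time effects, splits of 3 against 3 libraries number 10, too few for a share under 0.05, and the real count was 5 for AL WT (highest other 0), 0 for AL KO (highest other 174), 3 for TRF WT (highest other 19) and 0 for TRF KO (highest other 0). Chance can be excluded at a share under 0.05 for feeding, 1 of 100 (2956 real, highest other 205). It cannot be excluded for TRF genotype, 9 of 100 (1 real, highest other 26). Beside a real count of 0 every split has at least as many, so the splits decide nothing for AL genotype, 100 of 100 (0 real, highest other 416); AL genotype by time, 100 of 100 (0 real, highest other 408); TRF genotype by time, 100 of 100 (0 real, highest other 26); WT feeding by time, 100 of 100 (0 real, highest other 12); KO feeding by time, 100 of 100 (0 real, highest other 150); all 3 factors, 100 of 100 (0 real, highest other 1). Splits of SCN libraries with 150 to 416 genes beside a real count of 0 point to a structure among these libraries other than the groups compared.

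Chance can be excluded for liver against heart at a share under 0.05 for AL WT, 1 of 30 (3102 real, highest other 2158); TRF WT, 1 of 30 (2016 real, highest other 1719). It cannot be excluded for AL KO, 5 of 30 (1 real, highest other 57); TRF KO, 2 of 30 (1737 real, highest other 2016).

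The first pattern weighed is the brain and atrial transcripts of the 3 AL WT CT12 hearts. In each of them at least 99.6% of the 464 brain genes lay within 2-fold of 1 share of their SCN level, and the levels followed the SCN across these genes with Spearman's rho of at least 0.968 (genes are not independent replicates). Against neuronal genes being raised in heart cells speaks that the set holds genes of neurons (Gad1), glia (Mobp) and the lateral hypothalamus (Hcrt, at 15.8 CPM) alike. Brain RNA in the libraries is consistent with these values, and may have entered at dissection, extraction or library preparation, which the labels do not separate. It does not account for every difference between times. Brain RNA at the highest share of 22.5% by neuronal genes (library 48) would give other genes a log2 change of -0.37, and at the mean share of the 3 libraries, 12.3%, one of -0.19. The median found among genes it would raise by at most 10% was -0.32, and 225 of those genes changed more than 2-fold. Smaller falls in AL WT hearts remain open to it. For the atrial genes, 6 of 6 were higher in each AL WT CT12 library than in each at CT0, as more atrial tissue in these samples would give, and the AL KO CT0 hearts held Myl7 at 722 CPM with no such brain share. Time of day as a cause of either was not tested apart from the group.

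The second pattern is that in liver and heart the 3-digit AL libraries often lay between the other 2 of their group (most often of the 3 in 6 of the 8 groups). They held the middle value in 40.3 to 60.5% of genes (mean 52.8%), where independent libraries give 33.3% (32.6 to 33.7% in simulated data). A simulated, somewhat uneven mixture of the others gave 75.3 to 76.0%, no yardstick for all of them. Fitted mixture weights ran from 0.56 and 0.44 (liver AL_KO_CT0_407) to 0.96 and 0.04 (heart AL_WT_CT12_404). The real libraries spread more widely than simulated ones: the 14 others in groups of 3 held it in 8.97 to 44.7% of genes in liver and 5.28 to 43.4% in heart, with the highest in both tissues above the lowest of the 3-digit libraries (44.3 and 40.3%). Pairs of libraries with 1 of them differed less, with a median spread over counting noise of 3.11 in liver and 2.44 in heart, against 12.7 and 4.83 for the other pairs. Around a blend of the other 2, the 3-digit libraries had a spread of 1.44 to 2.44 in liver and 1.32 to 1.92 in heart. The 14 others had 1.95 to 24.3 and 1.35 to 47.8. In simulated data, independent libraries gave 20.5 to 21.5 and mixtures 0.970 to 0.994. The 3-digit library lay closest to a blend in 7 of the 8 AL groups of liver and heart. Material shared with the other libraries of the group is a candidate explanation. It was tested with Capn11 and Klk1b22, which follow the number across tissues in the other 20 numbers. By these genes, liver and heart of 2 of the 4 numbers, AL_WT_CT0_401 and AL_KO_CT12_410, both lay nearer to a blend of the other 2 libraries than to the SCN library of their number, as shared material would give, and so did 1 of the 20 others. From that SCN library, AL_WT_CT0_401 lay 1.19 SD away in liver and 1.16 in heart, and AL_KO_CT12_410 2.13 and 2.22, where the 20 others lay at 0.0870 to 1.16 and 0.0175 to 1.27. Liver and heart of AL_KO_CT12_410 thus do not match the animal of its SCN library by these genes. The test rests on 2 genes of low level, and 2 of 4 numbers decide neither way. In hearts, transcripts of other tissues went along with shared material in part. AL_WT_CT12_404 was close to 47 and far from 48 (Myl7 1044, 1094 and 130.2 CPM; brain share 8.14, 8.18 and 19.7%). AL_KO_CT0_407 was close to 56 and far from 57 (Myl7 459.8, 469 and 1238), and AL_KO_CT12_410 lay between 65 and 66 (Myl7 89.6, 0.372 and 277; Alb 48.6, 0.124 and 137). Brain transcripts went against it in AL_WT_CT0_401 and AL_KO_CT0_407, at 0.266 and 0.272% of their SCN level where the others of these groups had at most 0.0721 and 0.124%, unless they entered later. Shared material thus stays open. Against separate animals that lie between the others by chance speaks that of the 81 choices of 1 library from each AL group, only the 3-digit ones, singled out by number before the data were seen, gave as high a mean middle share over liver and heart (1 of 81, next highest 50.1%). In SCN, the same numbers gave the lowest mean middle share of the 81 choices (24.1%). Their spread around a blend was 4.22 to 7.83, above the lowest of the others (2.14), which argues against shared material in SCN. On the main SCN axis they scored -0.397 to 1.13, above the other AL libraries (-1.14 to -0.636). The SCN feeding effect was not fitted without them. If these libraries are not independent, the spread of the AL groups of liver and heart is too low and their counts too high. Without them the AL WT liver count was 356 in place of 1294. No biological explanation was tested.

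The third pattern is the SCN feeding effect, 2956 genes. Differences in dissection between the TRF and AL libraries may underlie part of it. The list of neuropeptides of nearby regions, set before the data were seen, was lower in TRF (fry adjusted p 0.00672), with 8 of 10 genes lower, as less neighbouring hypothalamus would give for all of them. Feeding may itself lower such genes, and the other region genes were chosen after their values were seen, so this explanation stays open. The main axis between libraries of the same group held 36.9% of their variance and correlated with the feeding effect across genes (r 0.78), but 114 of 1000 random divisions of the libraries gave as large a correlation (permutation p 0.114, median of the divisions 0.51), so this axis as the cause cannot be told apart from chance. With a term for it, 40 genes passed. The median size of the called genes went from log2 0.22 (median SE 0.06) to 0.12 (0.06), Pomc from -2.73 ± 0.53 to -1.42 ± 0.51, so the calls ended because the changes shrank and not because their spread grew. The feeding schedule itself stays open as a cause, since it cannot be told apart here from any difference between the TRF and AL dissections.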

How the results depend on the processing

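The fits without the 3-digit AL libraries, without genes that brain RNA would raise, without SCN libraries 1 and 10, and with a term for the main axis, and the list tests without heart library 48, were chosen after the results had been seen; the other alternatives were set before the data were examined. Of the counts of called genes under the alternatives set beforehand, other than leaving out 1 library, 121 of 179 stayed within 1.5 times the main count, as did 409 of 508 with 1 library left out. Of 147 results for named genes, none changed direction while called: 2432 of 2539 alternatives kept the call or its absence, 106 lost it (68 with 1 library left out, 20 in other fits set beforehand and 18 in those added) and 1 gained it. The lower Vip in SCN libraries labelled KO kept its direction with each library left out (log2 -2.94 to -2.50, permutation p 2.50e-05 to 1.50e-04) and with RLE factors (-2.70), and SCN Arntl stayed above p 0.05 (permutation p 0.234 to 0.587).

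The following counts of called genes moved by more than 1.5 times. Each stands with the effect or difference it counts, and the main counts stand in the text on each comparison. With RLE factors, the SCN count was 2 (TRF genotype). Without a filter on low counts, the liver counts were 5 (AL KO time), 992 (TRF genotype) and 14 (TRF genotype by time). The heart counts were 17 (AL KO time), 434 (TRF WT time), 329 (TRF KO time) and 241 (TRF genotype). The SCN counts were 8 (AL WT time), 7 (TRF WT time), 1 (AL genotype by time), 4 (TRF genotype), 2 (TRF genotype by time) and 2 (WT feeding by time). The liver against heart count was 1256 (TRF WT). With DESeq2, the liver counts were 31 (AL KO time), 339 (AL genotype by time), 63 (TRF genotype by time) and 248 (3 factors). The heart counts were 107 (AL KO time), 820 (TRF KO time), 842 (TRF genotype), 32 (TRF genotype by time) and 502 (KO feeding by time). The SCN counts were 20 (AL WT time), 63 (TRF WT time), 2 (AL genotype by time), 81 (TRF genotype), 13 (TRF genotype by time) and 23 (WT feeding by time). The liver against heart count was 19 (AL KO). With only the compared groups in the fit, the liver counts were 253 (AL KO time), 1622 (TRF WT time), 1934 (TRF KO time), 562 (AL genotype by time), 588 (TRF genotype) and 0 (TRF genotype by time). The heart counts were 3292 (AL WT time), 121 (AL KO time), 1278 (TRF WT time), 1126 (TRF genotype) and 510 (KO feeding by time). The SCN counts were 1 (AL WT time), 1 (AL KO time), 0 (TRF genotype) and 2 (WT feeding by time). Without TRF KO libraries 55 and 64, the liver counts were 1973 (TRF KO time) and 4 (TRF genotype by time). The heart counts were 113 (TRF KO time) and 119 (KO feeding by time). The SCN counts were 4 (TRF genotype), 1 (TRF genotype by time) and 1 (3 factors). The liver against heart count was 971 (TRF KO). With a term for the 3-digit AL libraries, the liver count was 479 (AL genotype by time). The heart counts were 1686 (AL genotype) and 2901 (AL genotype by time). Without the 3-digit AL libraries, the liver counts were 356 (AL WT time), 0 (AL KO time), 1134 (AL genotype), 26 (AL genotype by time), 2150 (WT feeding by time), 565 (KO feeding by time), 835 (feeding) and 16 (3 factors). The heart count was 1901 (AL genotype). The liver against heart count was 1858 (AL WT). Without genes that brain RNA would raise, the heart counts were 2214 (AL WT time), 730 (AL genotype), 1652 (AL genotype by time), 1467 (WT feeding by time), 922 (feeding) and 410 (3 factors). Without SCN libraries 1 and 10 of TRF WT, the SCN counts were 1 (TRF WT time), 0 (TRF genotype) and 1554 (feeding). With a term for the main axis between SCN libraries of a group, the SCN count was 40 (feeding), 33 of them among the 2956. Fits without a library, with a term or with only the compared groups test on fewer libraries or residual degrees of freedom. Fits without genes that brain RNA would raise test 4999 genes in place of 16397. Beyond this, the cause was not tested.

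Lowest and highest counts with 1 library left out are given where any moved by more than 1.5 times. Under this removal, the liver counts were 740 to 1305 (AL WT time), 0 to 10 (AL KO time), 2083 to 3329 (TRF WT time), 134 to 209 (AL genotype by time), 701 to 1736 (TRF genotype), 0 to 64 (TRF genotype by time), 1047 to 1771 (KO feeding by time) and 56 to 182 (3 factors). The heart counts were 0 to 56 (AL KO time), 248 to 767 (TRF WT time), 247 to 540 (TRF KO time), 137 to 524 (TRF genotype), 0 to 25 (TRF genotype by time) and 83 to 342 (KO feeding by time). The SCN counts were 0 to 3 (AL WT time), 0 to 5 (TRF WT time), 0 to 4 (TRF genotype), 0 to 1 (TRF genotype by time), 1839 to 3784 (feeding) and 0 to 1 (3 factors). The liver against heart counts were 1 to 6 (AL KO) and 1296 to 2187 (TRF WT). The cause was not tested beyond the loss of 1 library.

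Of the list tests called, 47 of 48 in liver, 43 of 46 in heart and 8 of 8 in SCN kept their call with RLE factors. Without TRF KO libraries 55 and 64, 43, 36 and 8 did (SCN holds 55 alone). Without the 3-digit AL libraries, 15 were called in liver and 29 in heart, each among those called before, and none turned. The heart lists lost are named in the text. Without heart library 48 of AL WT CT12, 70 were called in heart, 45 of them among the 46; the cause of the 25 gained was not tested.

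Liver and heart libraries share numbers. Of 26 numbers, 12 correlated above 0.1 across 6385 genes in their deviations from the group means (r -0.54 to 0.41), and 12 libraries correlated best with their own number. This check across genes does not show that the numbers pair the samples. A second check, made after the data were seen, used the 2 genes that varied most in all 3 tissues over the 20 numbers of fewer than 3 digits shared by liver, heart and SCN (SD of log2 above 1; predicted genes left out), Capn11 and Klk1b22. Within groups, both followed the number, Capn11 with r 0.81 between liver and heart, 0.79 between liver and SCN and 0.92 between heart and SCN, and Klk1b22 with 0.84, 0.97 and 0.85 (permutation p 0.001 with numbers exchanged within groups), as tissues of 1 animal under 1 number would give. With the number as a block in the comparison of liver with heart, the count was 2815 in AL WT, 3 in AL KO, 1573 in TRF WT and 1348 in TRF KO. In the 3 SCN libraries with 0 counts of Vip, no level under 0.163 to 0.178 CPM was detectable.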

Other observations

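All tests here were chosen after the results were seen. Less SCN tissue in the libraries labelled KO was tested as a source of their lower Vip. Over 13 other genes of the SCN, the KO minus WT log2 difference had a median of -0.03 and a lowest value of -0.90 (Prok2), while Vip was at -2.70. A lower share of SCN tissue as a whole thus does not account for Vip. Less of only the part of the SCN that makes Vip would not show in this test. Loss of Bmal1 in VIP cells, loss of such cells or an effect of the targeting construct on Vip could each give lower Vip and were not tested.

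Cold-inducible genes were higher in KO livers under AL and TRF and in KO hearts under TRF, and heat shock genes were lower in KO livers and hearts under TRF. The heat shock call in liver ended without the 3-digit AL libraries (fry adjusted p 0.0851). A lower body temperature of KO mice at collection is a candidate explanation. It would also raise the cold-inducible list in KO SCN, where the test under TRF gave an adjusted p of 0.45 (fry; 3 of 5 genes higher), which neither bears it out nor excludes it. In hearts under AL the list's adjusted p was 0.138.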
